A study of Homo sapiens with 2 samples.

How the data were processed

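RNA of RPMI8226 cells, an established human multiple myeloma line, was compared on 2 two-colour Agilent oligonucleotide arrays that lay on the same slide. On both arrays the Cy3 channel held RNA of untreated cells, per the labels. The Cy5 channel held RNA of cells cultured for 24 h with the stromal cell line UBE6T-7 on the first array, called the stromal adhesion array here. On the second it held RNA of cells given 1 µM PF-04691502, an inhibitor of PI3K and mTOR, for 24 h, per the labels. The labels do not say whether or how the myeloma cells were separated from the stromal cells before RNA was extracted. Per the labels' protocols, 50 ng of total RNA was amplified and labelled. Each condition was hybridised once, with no dye swap and no replicate array, so no test was made and no p-value is given. The number of arrays limits the precision of every value.

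Spot intensities on a linear scale were extracted with Agilent Feature Extraction 10.7.3.1, per the file headers and the submitters' processing notes, as the mean brightness of each spot and the median brightness of its local background. The deposited log10 ratios are log10 of Cy5 over Cy3 after that program's own background subtraction and dye normalization, per the file headers. The authors' value table of the whole series held the same log10 ratios, with a largest difference from the scanner files of 0 over 61657 spots and a median of 0 on each array, so its scale and direction were settled. Each array had 62976 spots, of which 1319 were controls, and 50683 different probes. Of the other spots, 42.0% were well above background in Cy3 on the stromal adhesion array and 42.3% on the PF-04691502 array. In Cy5 the share was 50.2% on both. No spot was saturated.

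From the intensities, background was corrected by normexp with an offset of 50 and the log2 ratio of Cy5 over Cy3 was normalized within each array by loess with a span of 0.3, in limma 3.58.1 under R 4.3.3 with version 1.17.8 of the data.table package. Control spots and spots marked as outliers, 739 and 777 of the non-control spots on the stromal adhesion and PF-04691502 arrays, had no weight, and outlier spots were then left out. The median log2 ratio removed in this way was 1.04 on the first array and 1.12 on the second. Loess takes most genes to be unchanged at each brightness, so a shift shared by most genes cannot be seen. Levels of single channels were set between arrays by Aquantile. Spots of a probe were averaged, and a gene took its probe with the highest mean signal over both arrays and channels. Other steps used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.

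Gene names came from a RefSeq table of assembly GRCh38.p14, used for names only. It named 28170 probes by accession, 2621 by symbol and 620 by an older symbol, and 19272 kept the name in the files, which gave 36484 genes. Probe coordinates are those of the files, on hg19 (GRCh37), per the file headers. The exon or UTR in which a probe lies was not worked out, since no annotation of that build was used here.

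A gene was counted as higher or lower when its treated and untreated levels differed at least 2-fold and both channels were well above background. A gene well above background in 1 channel has only a bound, given as "at least N-fold": the bright level over the higher of the dim level and the lowest signal among probes well above background in the dim channel. Where the dim level is the higher, the bound equals the measured ratio and is an estimate, not a strict lower limit. Such bounds stay open to dye bias, as do all ratios here. The lists of genes, 29 with 790 entries of which 789 were on the array, were fixed before the data were examined. They covered stromal and plasma cell markers, apoptosis, Polycomb, NF-κB, interferon, FOXO, sterol, amino acid, unfolded protein, glycolysis, hypoxia, DNA replication, mitosis, cell cycle inhibitors, ribosome biogenesis, ribosomal proteins, autophagy, p53, immediate early, detoxification, adhesion receptor, growth factor, PI3K and mTOR, antigen presentation, proteasome and respiratory chain genes. A list's median log2 ratio, over members well above background in at least 1 channel, is given with its percentile among 10000 random lists of the same size matched on mean signal in 10 bins, as a description of that array. A median below the 2.5th or above the 97.5th percentile is called outside the range of random lists.

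The genes named were also fixed by rule before the data were examined. They are, per array, the 10 highest and 10 lowest genes with a symbol, lincRNAs left out, measured in both channels, the 3 largest bounds in each direction, up to 4 members of each list with the largest absolute log2 ratio, 7 genes of interest to the study (EZH2, IGF1, BCL2, HIF1A, IGF1R, IRF4 and MYC), and the 5 per direction furthest apart among genes that differed at least 1.5-fold in opposite directions on the arrays. The text gives some of these genes and leaves others out. The ranks were first taken among protein-coding genes, a narrowing made after the data were examined. The genes the rule as written adds are given as well, and UNG, CYP24A1, SNN, LPGAT1, MT1B, RNASE6 and PLSCR1 are named from the narrower ranks. Other genes outside the rule are marked as chosen after their values were seen.

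The normalization was tested on simulated data made from the real Cy3 signals. At a true log2 ratio of 1.5, 43 of 50 probes made higher (86%) passed 2-fold for the stromal adhesion array and 41 of 50 (82%) for the PF-04691502 array. Only probes that stayed well above background were scored, 25681 and 25829 in all, changed and unchanged. Of those made lower by as much, 32 of 39 (82.1%) and 32 of 36 (88.9%) passed. At 2.5 all 50 made higher passed for both, as did all of the 29 and 35 made lower that were scored. Lowered probes lost to the background are not in these shares. Of the unchanged probes 0 passed, but the simulated noise was small and held no dye bias of single probes. This result therefore does not measure false 2-fold calls in the real data. Of 200 random lists of 25 genes, 7.0% on the stromal adhesion array, over 12741 genes, and 3.5% on the PF-04691502 array, over 12850 genes, lay outside the range. The alternatives tried were another normexp offset, no background subtraction, Feature Extraction's own ratio, the authors' value table, median centring over probes well above background in both channels, other filters on dim probes and outlier spots, the median over a gene's probes, and thresholds of 1.5-fold and 3-fold.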

Results

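The series asked which genes of RPMI8226 myeloma cells differ in level when the cells adhere to stromal cells, and which when they are given PF-04691502. There was 1 array for each question, each set against untreated cells, so differences are described by size and carry no replicate error.

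The only condition measured more than once was the untreated Cy3 channel. Over the 15192 genes well above background in all 4 channels, its log2 level differed between the arrays with an SD of 0.134, and 99% of genes differed by less than 0.374. Whether these channels were 1 extract or separate cultures is not in the labels, so this is the spread between hybridisations and can leave out that between cultures. Spots of one probe had a median SD of 0.063 in log2 ratio on the stromal adhesion array, over 594 probes, and 0.065 on the PF-04691502 array, over 590 probes. The 10 spike-in probes gave ratios within 0.0787 of each other on the arrays. Feature Extraction's slope of observed on expected spike-in ratio was 0.883 on the stromal adhesion array and 0.882 on the other. The log2 ratios had an SD of 0.23 for stromal adhesion and 0.49 for PF-04691502, and 8.71% and 33.9% of genes lay beyond that 99th percentile. That percentile compares Cy3 with Cy3, whereas the ratios set Cy5 against Cy3 and also carry dye bias of the probes. These shares are therefore not counts of genes beyond technical noise.

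**Figure D1:**
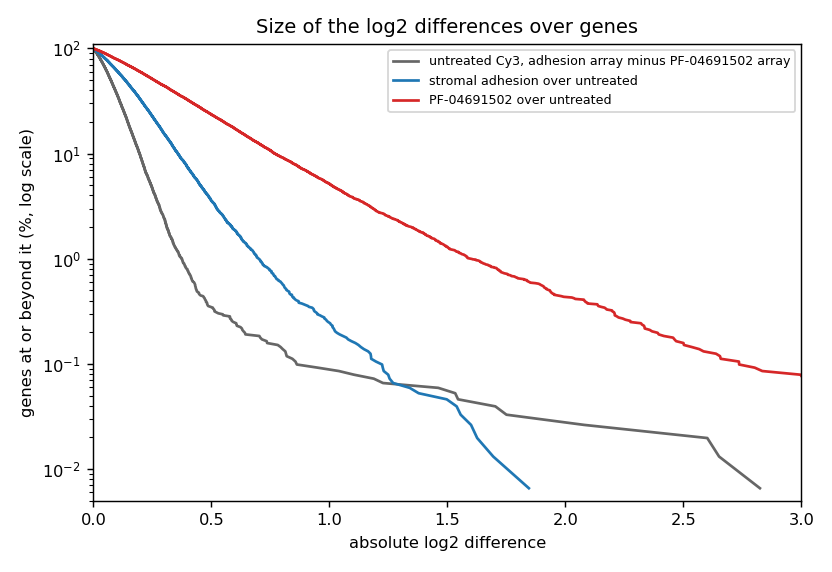
Share of the 15192 genes (%, log scale) at or beyond each absolute log2 difference. The grey line is the difference of the untreated Cy3 channels, the blue line stromal adhesion over untreated and the red line PF-04691502 over untreated. The red line lies above the others throughout, and 13 genes differ at least 2-fold between the untreated channels.

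Cells cultured with stroma had higher levels of interferon-response genes and lower levels of DNA replication genes than untreated cells. Of 26 measured interferon-response genes, 13 were at least 1.5-fold higher, 3 were at least 2-fold higher and 0 were at least 1.5-fold lower, with a median log2 ratio of 0.58. IFIT1, an interferon-induced RNA-binding protein, was 3.09-fold higher (accession NM_001548 in the files, probe on chromosome 10 at 91163438 to 91163497, hg19). OASL was 2.82-fold and IFIT2 2.53-fold higher. Over the settings tried, the log2 ratio of IFIT1 lay between 1.53 and 2.39 and that of IFIT2 between 0.78 and 2.41. MX1, an antiviral GTPase, was at least 1.88-fold higher with the settings used here, as it was not well above background in untreated cells. Its log2 ratio lay between 0.43 and 3.85 over settings, against 0.64 to 3.95 on the PF-04691502 array. Of 35 DNA replication genes, 33 were lower and 7 were at least 1.5-fold lower, with a median log2 ratio of -0.46. UHRF1, which maintains DNA methylation at replication, had a log2 ratio of -0.82. GINS2, MCM4 and DTL had -0.72, -0.68 and -0.68. The interferon median lay above all random lists and the replication median below all of them. On the PF-04691502 array, in the same dye orientation, the interferon median was also above the range, at 0.39 with the settings used here. Over the 20 interferon-response genes measured in all 4 channels, the median difference between the arrays was 0.18, and 8 had opposite signs. The replication genes had a similar median, -0.395, on the PF-04691502 array in the same dye orientation, although 11 of the 35 had opposite signs. For both lists dye bias or a shared control cannot be told apart from an effect of stroma. Of 40 markers of stromal cells, 15 were measured and 1, TGFBI, was at least 1.5-fold higher, with a list median of 0.02. COL1A1, COL1A2, COL3A1 and SPARC, chosen after their values were seen, were not well above background in either channel.

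In all, 20 genes were at least 2-fold higher and 19 lower among the 15778 measured in both channels of the stromal adhesion array. HSD11B1, which converts cortisone to cortisol, was the highest at 3.59-fold (NM_181755, chromosome 1, 209907901 to 209907960, hg19). The complement factors CFI and C4B had log2 ratios of 1.69 (1.08 to 2.82 over settings) and 1.54, and C4B has a near-identical copy, C4A, from which its signal may not be separable. SPP1, which encodes osteopontin, was 3.03-fold higher, and its untreated level itself differed by -0.64 between the arrays, beyond the 99th percentile. CHRD, a BMP antagonist, BIRC3, an inhibitor of apoptosis, and TGFBI, an extracellular matrix protein, had 1.25, 1.18 and 1.18. On the PF-04691502 array, in the same dye orientation, HSD11B1 (0.71 to 0.94 over settings), CFI, C4B, CHRD, BIRC3 and TGFBI were higher too. IFIT1, OASL, IFIT2 and SPP1 were lower there. With adhesion, the cholesterol transporter ABCA1 was at least 1.76-fold higher with the settings used here, with a log2 ratio of 0.30 to 3.24 over settings. The lowest gene was TNFRSF17, the BCMA receptor of plasma cells, at 2.94-fold lower (NM_001192, chromosome 16, 12061768 to 12061827, hg19). The chemokine receptor gene CXCR3 had a log2 ratio of -1.38, but another measured probe of it had -0.17. Next after KLF2 came 6 near-identical small noncoding RNAs, SNAR-B2, SNAR-D, SNAR-G2, SNAR-H, SNAR-A3 and SNAR-F, at -1.16 to -1.25. KLF2 was 2.41-fold lower, and UNG, a uracil-DNA glycosylase, was 2.18-fold lower. SNN, LPGAT1, MT1E and NCAM1 had log2 ratios of -1.09, -1.08, -1.07 and -1.02, and another measured probe of MT1E had -0.17 and of NCAM1 -0.34. STRA6 and CYP24A1 also ranked among the lowest, at -1.15 and -1.11, but their untreated levels were well above background on this array and not on the other, and their spots lie close together on the slide. Over settings, CXCR3 ranged from -1.49 to -0.77, NCAM1 from -1.14 to -0.35 and CYP24A1 from -1.49 to -0.45. FAM169A, HLTF and CD3E were at least 1.43-fold, at least 1.42-fold and at least 1.38-fold lower, with log2 ratios over settings of -2.02 to -0.26, -1.36 to -0.46 and -1.37 to -0.39. With Feature Extraction's own ratios, 61 genes were higher and 102 lower, 37.4% higher against 51.3%. On the PF-04691502 array, TNFRSF17 (-3.61 to -2.73 over settings), LPGAT1 (-1.02) and NCAM1 (-1.95) were lower too. UNG and MT1E were higher there, at 0.90 and 1.14, as was KLF2, and SNN had -0.02. For genes that differed the same way on both arrays, dye bias or a shared control cannot be told apart from an effect of stroma. A stromal source of single higher genes was not tested.

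Other lists lay outside the range of random lists by smaller amounts on the stromal adhesion array. Plasma cell genes were lower in 16 of 21, with a median of -0.16, among them CD38 at -0.83 and the syndecan gene SDC1 at -0.59. Ribosome biogenesis genes were lower in 26 of 34 (median -0.10, RRS1 at -0.50). Medians were above the range for amino acid response genes (0.15, CHAC1 at 0.61), FOXO targets (0.18, BCL6 at 0.78 and KLF2 the other way at -1.27), antigen presentation (0.19, TAP1 at 0.50), glycolysis (0.10, PKM at 0.50), mitosis (0.12, PLK1 at 0.40) and ribosomal proteins (0.10, RPS2 at 0.36). Another 5 measured probes of RPS2 ranged from -0.23 to 0.36. The other 19 lists lay within it. Their medians were 0.02 for stromal markers, 0.10 for anti-apoptotic and -0.07 for pro-apoptotic genes, 0.05 for PRC2 and H3K27 genes, -0.04 for developmental Polycomb targets, 0.07 for NF-κB targets, 0.00 for sterol and lipid genes, -0.03 for the unfolded protein response, -0.03 for hypoxia targets, -0.02 for cell cycle inhibitors and D cyclins, 0.04 for autophagy and lysosome, 0.02 for p53 targets, 0.03 for immediate early genes, -0.08 for drug transport and detoxification, 0.05 for adhesion receptors, -0.07 for growth factors and receptors, 0.04 for PI3K and mTOR components, -0.09 for the proteasome and -0.00 for the respiratory chain. With median centring in place of loess, the plasma cell median became 0.06 and that of ribosome biogenesis 0.09, both still below the range of random lists (percentiles 1.09 and 0.85). FOXO targets and mitosis came within the range. FOXO targets also came within it, with medians of 0.10, 0.10 and 0.09, with list members measured in both channels, with no filter on dim probes and with the median over a gene's probes. Mitosis did so without background subtraction (median 0.09) and with Feature Extraction's own ratios (0.09), and ribosomal proteins with the latter (-0.004). In turn, lists came outside the range: drug transport and detoxification in 4 of 9 settings (-0.46 with median centring) and growth factors and receptors in 4 (-0.19 with median centring). For the latter, the 4 include Feature Extraction's own ratios and the authors' value table, which hold the same values. Immediate early genes (-0.10 with no filter on dim probes) and cell cycle inhibitors and D cyclins (-0.17 with median centring) did so in 1 each. Plasma cell genes, FOXO targets and ribosomal proteins lay outside the range in the same direction on the PF-04691502 array, at -0.70, 0.39 and 0.27. For these lists dye bias or a shared control cannot be told apart from an effect of stroma. Amino acid response, glycolysis and mitosis genes lay outside it in the other direction there.

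**Figure D2:**
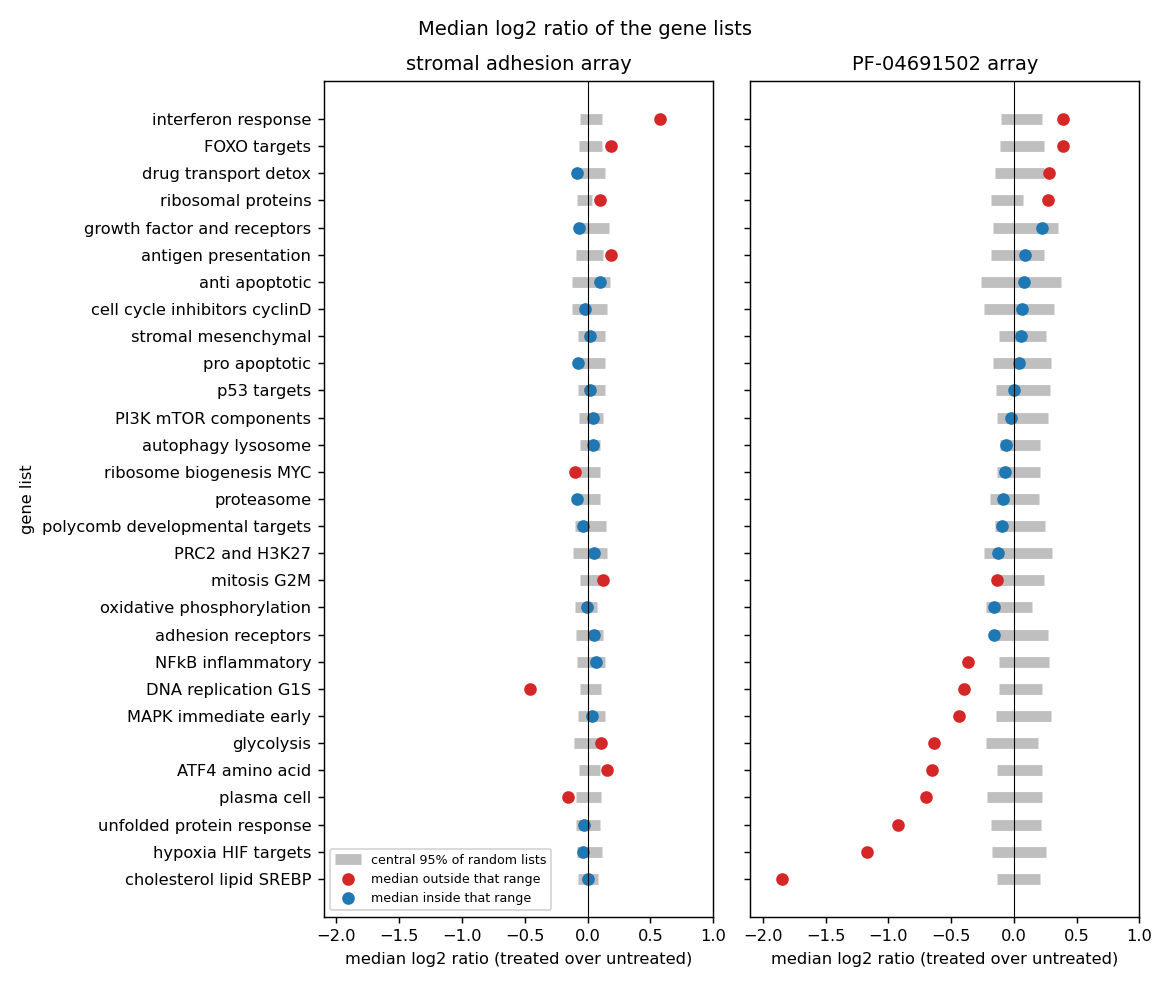
Median log2 ratio (treated over untreated) of each of the 29 gene lists on the stromal adhesion array (left) and the PF-04691502 array (right). Grey bars span the central 95% of random lists matched on signal, red points lie outside that span and blue points inside it. Interferon-response genes reach 0.58 with adhesion, and sterol genes -1.84 with PF-04691502.

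Cells given PF-04691502 had much lower levels of sterol and lipid synthesis genes than untreated cells, and lower levels of hypoxia targets, unfolded protein response, plasma cell, amino acid and glycolysis genes. Of 32 sterol and lipid genes, 28 were at least 1.5-fold and 24 at least 2-fold lower, with a median log2 ratio of -1.84. INSIG1, which retains the SREBP processing complex in the endoplasmic reticulum, was 24.9-fold lower (NM_005542, chromosome 7, 155101843 to 155101902, hg19). HMGCS1, an enzyme of the mevalonate pathway, was 10.9-fold lower, and FDFT1 and MSMO1 had log2 ratios of -3.00 and -2.83. Of 23 hypoxia targets, 19 were at least 1.5-fold lower (median -1.17), with HILPDA at -3.32, ADM at -2.73 and the glucose transporter SLC2A1 at -2.58, which was -1.34 by the median over its probes. Of 25 unfolded protein response genes, 16 were at least 1.5-fold lower (median -0.93, HERPUD1 at -1.58 and SDF2L1 at -1.37). Of 31 amino acid response genes, 17 were (median -0.65, CHAC1 at -1.67 and PSAT1 at -1.50, with another measured probe of PSAT1 at -0.76), as were 11 of 21 glycolysis genes (median -0.64, HK2 at -1.48). Plasma cell genes had 10 of 20 at least 1.5-fold lower (median -0.70), with TNFRSF17 6.66-fold lower and ITGB7 at -1.95, whose untreated level differed by -0.64 between the arrays. POU2AF1 had -1.76, but another measured probe of it had 0.33.

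In all, 384 genes were at least 2-fold higher and 405 lower among the 15845 measured in both channels, and 25 higher and 5 lower by their bounds. KLHDC9 was the highest at 6.31-fold (NM_001007255, chromosome 1, 161070036 to 161070095, hg19), with a log2 ratio of 2.66 to 3.79 over settings, followed by DEPP1, a FOXO target, at 5.92-fold. SAMD9L, SERPINB1, TP53INP1 and CTSF had log2 ratios of 2.42, 2.09, 2.09 and 2.08, and TRAF3IP3, ELF3, SOCS3 and KIF3A 2.04, 2.03, 1.90 and 1.84. Other measured probes had 1.45 for TP53INP1 and 1.44 to 1.88 for TRAF3IP3. ABCA1 was at least 3.50-fold higher, RIMBP3 at least 2.97-fold, the pseudogene TOB2P1 at least 2.71-fold and PLSCR1 at least 2.57-fold. Over settings their log2 ratios ranged from 1.05 to 3.67, 1.34 to 4.12, 1.21 to 3.15 and 1.16 to 2.82, so that these bounds hold only for the settings used here. For TOB2P1 and PLSCR1 the bound equals the measured log2 ratio, 1.44 and 1.36, so it is no strict lower limit. After INSIG1, the lowest were the pseudogene CXCR2P1 at -4.48, the chemokine CXCL8, 19.6-fold lower, RGS1, 14.7-fold lower, and IGFBP3 at -3.66. Another measured probe of CXCL8 had -1.67. CYTIP, ADCY1, VAV3 and RNASE6 had -3.38, -3.19, -3.04 and -3.01. Over settings, CXCL8 ranged from -5.00 to -2.98, TNFRSF17 from -3.61 to -2.73, MSMO1 from -3.90 to -2.83, POU2AF1 from -1.76 to -0.71, ELF3 from 2.02 to 2.98, KIF3A from 1.01 to 2.28, OAS1 from 1.70 to 2.53, BMF from 0.99 to 1.83 and BCL2L11 from 0.37 to 1.48. CHAC1 ranged from -2.5 to -0.95, with -2.23 at a normexp offset of 0 and -0.95 by the median over its probes. CCDC39, MPEG1 and PTPRO were at least 2.85-fold, at least 2.41-fold and at least 2.33-fold lower, with log2 ratios over settings of -4.04 to -1.61, -3.73 to -0.93 and -3.79 to -1.31. Of 253 genes with several measured probes and at least 1 of them 2-fold different, 41 (16.2%) had probes of opposite sign, against 0 of 10 on the stromal adhesion array. Some of the highest genes were also higher with adhesion, over settings: SOCS3 (1.03 to 1.26), TP53INP1 (0.96 to 1.31), ELF3 (0.76 to 1.89), SERPINB1 (0.72 to 0.92), TRAF3IP3 (0.65 to 0.90) and SAMD9L (0.41 to 0.71). DEPP1 (0.26 to 0.45) and CTSF (0.23 to 0.25) were less so, and KLHDC9 and KIF3A turned sign. For genes that differed the same way on both arrays, dye bias or a shared control cannot be told apart from an effect of the drug.

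Several lists of cell signalling genes also lay outside the range on the PF-04691502 array. FOXO targets were higher in 21 of 26 (median 0.39), with TXNIP at 1.71, KLF2 at 1.32 and CITED2 the other way at -1.63. Ribosomal proteins were higher in 44 of 47 (median 0.27, RPS27 at 0.63), although other probes of RPS27 ranged from -0.13 to 0.42. Drug transport and detoxification genes had a median of 0.28, with GCLC at 1.25. Interferon-response genes had a median of 0.39 with OAS1 at 1.75. With median centring in place of loess their median was -0.01, which came within the range. Immediate early genes were lower in 19 of 21 (median -0.44, EGR1 at -2.21). DNA replication genes were lower in 26 of 35 (median -0.39, MCM7 at -0.98) and mitosis genes in 22 of 32 (median -0.14, CDK1 at -1.03). Other measured probes of MCM7 and CDK1 had -0.39 and -0.32. NF-κB targets had a median of -0.36, which came within the range with median centring and with no filter on dim probes. Of the lists within the range, anti-apoptotic genes had a median of 0.08 and pro-apoptotic genes 0.04, with BMF at 1.66, BCL2L11 at 1.31 and PMAIP1 at -1.35. Other measured probes had 0.33 for BMF and 0.34 to 0.38 for BCL2L11. The medians were -0.13 for PRC2 and H3K27 genes (PHF19, 5.66-fold lower), -0.10 for developmental Polycomb targets, 0.06 for stromal markers (FN1 at -2.46), 0.07 for cell cycle inhibitors and D cyclins, -0.07 for ribosome biogenesis, -0.06 for autophagy and lysosome (CTSB at 1.67, GLA at -1.60), -0.00 for p53 targets, -0.16 for adhesion receptors, 0.22 for growth factors and receptors, -0.02 for PI3K and mTOR components, 0.08 for antigen presentation, -0.09 for the proteasome and -0.16 for the respiratory chain. Adhesion receptors came outside the range with median centring, at -0.17.

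Of the genes of interest to the study, EZH2, the H3K27 methyltransferase, had log2 ratios of 0.12 with adhesion and -0.08 with PF-04691502 (NM_004456, chromosome 7, 148504505 to 148504564, hg19), both within the spread of the untreated channels. HIF1A had 0.13 and -0.10, MYC -0.34 and -0.22, IRF4 -0.25 and -0.20, and IGF1R -0.16 and 0.22, each within that 99th percentile. Among genes of high signal, such as MYC, the percentile was 0.258, which MYC exceeded with adhesion. Neither percentile takes in dye bias, so a place within or beyond it does not settle whether a gene differs. Another measured probe of HIF1A had -0.28 and -0.21. BCL2, an inhibitor of apoptosis, had 0.10 with adhesion and was 1.68-fold lower with PF-04691502, over 8 spots with an SD of 0.053. Another measured probe of BCL2 had -0.36 and -1.25. IGF1 was not well above background in both channels of either array, and its log2 ratio with adhesion turned sign over settings, from -0.53 to 0.43.

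Compared with each other, the arrays differed most in sterol and hypoxia genes, and 632 genes were at least 2-fold apart, 394 of them higher on the stromal adhesion array. The median difference, adhesion minus PF-04691502, was 1.76 for sterol genes, 1.05 for hypoxia targets, 0.87 for glycolysis, 0.81 for the unfolded protein response and 0.79 for amino acid response genes. For DNA replication genes, whose median was low on both arrays, the median difference was -0.07. Genes that differed at least 1.5-fold in opposite directions numbered 29, of which 22 were protein-coding. By direction, 15 were higher with adhesion and 14 lower, against 15.0 and 11.5 for independent lists. Among them CSF1R had 0.63 with adhesion and -2.39 with PF-04691502, SPP1 1.60 and -1.27, BHLHE22 0.91 and -1.39, CHAC1 0.61 and -1.67, and DDIT4, an mTOR inhibitor, 0.67 and -1.31. The pseudogene FCGR1BP had 0.63 and -1.94, but another measured probe of it had -1.03 with PF-04691502, and its ratio there lay between -2.58 and -1.15 over settings. In the other direction KLF2 had -1.27 and 1.32, and the metallothioneins MT1G, MT1E and MT1B had -0.87 and 1.53, -1.07 and 1.14, and -1.02 and 1.06, with another measured probe of MT1E at -0.17 and 0.30. The metallothionein MT2A was 1.93-fold lower and 2.46-fold higher, and the pseudogene MT1L had -1.01 and 1.07. These metallothioneins are near-identical, so their probes may share signal.

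Over the 15192 genes, which are not independent replicates, the log2 ratios of the arrays had a Pearson r of 0.35 and a Spearman rho of 0.365. Their covariance was 0.0393, against 0.00905 in 100 simulations of unchanged groups with 1 shared control. In such simulations r is 0.50 by construction, and the covariance is set by the spread between the untreated channels alone. Of genes at least 2-fold higher, 9 were shared, against 0.499 for independent lists, and of those lower 4, against 0.453. In opposite directions 1 gene was higher with adhesion and lower with PF-04691502, against 0.533, and 4 the reverse, against 0.424, of which MT1E, MT1B and MT1L are near-identical. At 1.5-fold, 81 were higher on both, against 20.9, and 44 lower on both, against 8.27. Part of the excess can come from a shared control or from dye bias, since the controls cannot be split and no dye was swapped.

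**Figure D3:**
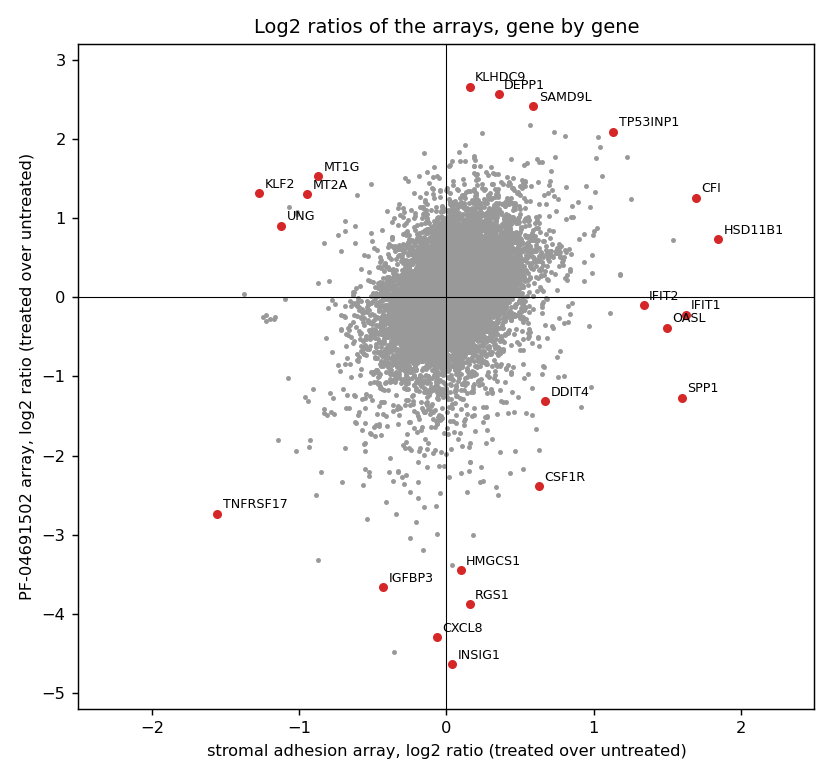
Log2 ratio (treated over untreated) of each of the 15192 genes on the stromal adhesion array (x axis) and the PF-04691502 array (y axis). Each grey point is a gene and labelled red points are some of the genes named in the text. TNFRSF17 lies low on both, at -1.56 and -2.74, and KLF2 lies low on one and high on the other.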

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

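No paired analysis was possible because each condition was hybridised once, and for the same reason no array could be left out. Leaving out genes with a discordant untreated level, the both-channel filter on list members and Gquantile scaling were chosen after seeing the data. The counts depended on the background correction, the ratio and the threshold. With a normexp offset of 0, 41 genes were higher and 34 lower with adhesion and 618 and 611 with PF-04691502, 1051 were 2-fold apart and 24 were shared. With Feature Extraction's own ratios, and alike with the authors' series matrix values, these were 61 and 102, 792 and 798, 1402 and 45, and r was 0.316. With median centring in place of loess, 50 were higher and 70 lower with adhesion, r was 0.424 and 24 were shared. With the median over the probes of a gene, 13 were higher with adhesion, 254 were higher with PF-04691502 and 5 were shared. With no filter on dim probes, r was 0.313. At 1.5-fold the counts were 198 and 117 with adhesion and 1618 and 1155 with PF-04691502, and at 3-fold they were 4 and 0, and 37 and 119. The threshold sets those counts by construction, and the cause of the other differences was not tested. Some values turned sign. The ribosomal protein median with adhesion was -0.004 with Feature Extraction's own ratios and with the series matrix values. With median centring, the plasma cell and ribosome biogenesis medians with adhesion were 0.063 and 0.089, though both lists stayed below the range of random lists in all 9 settings, and the interferon median with PF-04691502 was -0.015. FLCN, lower on both arrays by its brightest probe, had 0.07 with adhesion and 0.05 with PF-04691502 by the median over its probes. Interferon-response genes kept a median of 0.478 to 0.741 and DNA replication genes of -0.469 to -0.294 with adhesion over 9 settings, and sterol genes -1.87 to -1.66 with PF-04691502, all outside the range of random lists. Without the genes of discordant untreated level, 20 were higher and 17 lower with adhesion, as STRA6 and CYP24A1 drop out. Over all settings, list medians moved by less than the spread of random lists in 418 cases, by more in 99 and reversed in 5. Those 5 are the sign changes given above, of lists outside the range of random lists. Medians of lists within the range changed sign as well and are not among the 5. With adhesion and median centring, p53 targets went from 0.021 to -0.192 and stromal markers from 0.016 to -0.519. Of 227 named genes, 29 with adhesion and 46 with PF-04691502 had a log2 ratio that differed by over 1.5-fold from the one reported in at least 1 setting, among them IFIT2, CFI, KLHDC9 and SLC2A1. With Gquantile scaling the SD of the untreated difference was 0.129. Signal limits the rest: 3251 genes on the stromal adhesion array and 3266 on the other were well above background in 1 channel only.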

Other observations

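Of the tests in this part, only the comparison across different probes of a gene was set before its result was seen. The bound for randomly drawn genes in the first pattern was reset after their value had been seen, and its other-probes test was limited to probes above background after a first look. SNAR-C4, SNAR-G1, NEAT1, CXCL9, GRM4 and metallothioneins outside the rule were chosen after their values were seen.

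A group of small noncoding RNAs stood among the lowest with adhesion. SNAR-A3, SNAR-B2, SNAR-D, SNAR-F, SNAR-G2 and SNAR-H, small RNAs that bind the protein NF90, had log2 ratios of -1.17, -1.25, -1.23, -1.16, -1.22 and -1.20 with adhesion, and of -0.27, -0.25, -0.30, -0.25, -0.22 and -0.28 with PF-04691502. These copies are near-identical, so their values count as 1 signal. SNAR-C4 and SNAR-G1, much dimmer, had -0.13 and -0.19 with adhesion. With median centring in place of loess the 8 lay between -0.96 and -0.29. The long noncoding RNA NEAT1 had 1.23 with adhesion and 1.77 with PF-04691502. The interferon-induced chemokine CXCL9 had 1.11 and -0.20. All 8 metallothioneins measured in the 4 channels were lower with adhesion and higher with PF-04691502, and with median centring 7 of the 8 were lower with adhesion.

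The first pattern is a set of 146 genes, dim ones included, whose untreated level differed at least 2-fold between the arrays, 142 of them higher on the PF-04691502 array. Local defects on the slide surface are a candidate explanation: 89.0% of these genes had another of them within 3 rows and 3 columns, against a median of 10.3% and an upper limit of 17.8% in 1000 random draws. STRA6, CYP24A1 and GRM4 lay together between rows 155 and 159 of the stromal adhesion array. They belong to the 4 genes higher on that array, so they are not an example of the 142. Untreated RNA that differs between the arrays stays open, since other probes above background existed for 8 of these genes only, with a median absolute difference of 0.12.

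The second pattern is the set of 13 interferon-response genes at least 1.5-fold higher with adhesion. The carry-over of stromal cell RNA would bring abundant stromal transcripts, but 1 of 40 stromal markers was well above background in Cy5 and at least 1.5-fold higher. That marker was TGFBI, which is among the 10 highest protein-coding genes of the array and was also well above background in untreated cells. COL1A1, COL1A2 and COL3A1 were not above background. Of the 40, 15 were well above background in Cy5 and 9 in Cy3, that is, already in untreated cells. Over all non-control spots of that array Cy5 was also more often well above background, 50.2% against 42.0%. Dye bias of the probes cannot be told apart from an effect: the median difference from the PF-04691502 array was 1.08, with a bootstrap interval of 0.132 to 1.54, which reaches below the bound of 0.2 set for the test, although 7 of the 13, with 3 near-identical IFITM genes among them, were below 0 on that array in the same dye orientation and 3 were at least 1.5-fold higher there. These genes were picked for a high ratio with adhesion, which raises that difference, and over the 20 interferon-response genes measured in all 4 channels the median difference was 0.18. The drug has effects of its own and no dye was swapped, and an effect of the co-culture on the myeloma cells, which the design names, is untested.

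The third pattern is the positive covariance of the log2 ratios of the arrays. Base composition of the probes stays open: r was 0.35 after regression on base counts and signal, but the regression took up 0.692% of the variance on the stromal adhesion array and 1.22% on the other, too little to move r. Dye bias of single probes was left undecided: over 3085 genes, the covariance between different probes of a gene was 0.42 of that of the same probe, with an interval of 0.349 to 0.479, between the bounds set for either outcome. A shared untreated control also stays open, since the covariance exceeded the simulated one by 0.03 but the labels do not say whether the untreated channels were separate cultures. A response common to adhesion and the drug is untested.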
